A study of Mus musculus with 12 samples.

How the data were processed

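Gene expression was measured in 12 mouse tumors, each on its own Affymetrix 1-color oligonucleotide array with 45101 probe sets. Per the labels' protocols, LLC cells (Lewis lung carcinoma, a mouse lung cancer line) were placed under the skin of the right flank of female C57BL/6 mice aged 6 to 8 weeks. Mice were allotted to treatments at a tumor volume of 60 to 80 mm3, tumors were taken on day 19, and biotin-labelled cRNA was made from 6 µg of total RNA. The labels name 4 groups of 3 tumors. Control tumors received the antibody 13C4, 1D11 tumors received the antibody 1D11, radiation tumors received 13C4 with radiation, and 1D11_radiation tumors received 1D11 with radiation. 1D11 binds and neutralizes TGF-beta, and 13C4 is its isotype control. The labels disagree on the dose: the sample characteristics give 5 fractions of 6 Gy, and the sample descriptions give 2 Gy. The descriptions also speak of cells, where the source names speak of tumors; the values are treated here as those of whole tumors.

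The deposited values are intensity summaries per probe set on a linear scale, and the background correction, normalization and summary software are not given in the sources used here. Values ran from 7.40 to 30800, and no value lay below the floor of 1. Array medians lay between 62.3 and 66.1, and sorted log2 values of any pair of arrays differed by at most 0.129. The deposited values were therefore already normalized between arrays and were used as log2 intensity without a further step. No raw image files were used, so background signal per array is not known. The number of arrays, 3 per group, limits the precision.

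The probe table paired 34945 probe sets with a single gene symbol, 932 with several symbols and 9160 with none, and 64 control probe sets were left out. Of the 18193 genes with a probe set, 9010 had more than 1, and each gene was represented by the probe set with the highest mean log2 value over the 12 arrays. Genes in the lowest 30 percent of gene means, below a log2 value of 5.37, were not tested, which left 12735 genes. Trp53, Isg15, Bax, Gdf15, Spp1 and Fbn1 have no probe set with a single symbol and are not analysed here.

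Groups were compared in R 4.3.3 with limma 3.58.1: lmFit with 1 mean per group over all 12 arrays, then eBayes with default settings (8 residual and 3.11 prior degrees of freedom). Tests were two-sided, and a gene is called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The contrasts were the 4 differences between groups that share an antibody or a radiation state, 1D11_radiation against control, the interaction, and both main effects of 6 against 6 tumors. The interaction is the effect of radiation under 1D11 minus the effect of radiation under 13C4. Errors of log2 changes are standard errors (SE) from that model, with n = 3 tumors per group.

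32 gene lists of pathways, cell types, neighbouring tissue and RNA quality were tested with limma's camera at a preset correlation of 0.01. Adjustment ran over the lists within each contrast. camera compares a list with the other genes. It was repeated with an estimated correlation, and limma's fry, which tests whether a list's genes move one way without a comparison to other genes, was run beside it. The red blood cell list had fewer than 5 tested members and was not tested, so 31 lists remained. The score of a list in a tumor is the mean of its members' log2 values, each centred over the 12 arrays. Scores were also compared by exact permutation of the treatment labels for both main effects, a test added after the data had been seen. For the interaction, relabelings of all 12 tumors do not hold antibody and radiation fixed, so no p from them is given. Counts within a list are given over all genes tested and adjusted over the list alone.

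The genes named per contrast were the 10 largest rises and falls among called genes, or all called genes where fewer passed, or the 3 with the smallest unadjusted p in a direction where none passed. For the main effects and the interaction they were the 5 with the smallest p in each direction. Up to 4 members with the smallest p in each list described, and Tgfb1, Tgfb2, Tgfb3, Tgfbr1, Tgfbr2, Smad7, Cdkn1a and Mdm2 in every contrast, were added. A gene named outside this rule is given as such. The groups, contrasts, tests, filters, gene lists, this naming rule and most alternatives were chosen before the data were examined. Leaving out both arrays with the most skeletal muscle signal, and the muscle or keratinocyte score as a covariate, were alternatives chosen after seeing the data.

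Replicate numbers were not used as pairs or batches. Across genes, arrays with the same number in different groups correlated at r from -0.31 to 0.27 after removal of group means, and 3 of 18 such pairs were over 0.1. No array was a copy of another: the SD of log2 differences between arrays was at least 0.170, and r across genes ran from 0.976 to 0.996. The labels give no array date or batch. The procedure was tested on simulated data with the spread of these arrays. It recovered 66% of 50 genes at a log2 change of 0.5, 96% at 1, 98% at 2 and 100% at 4, called 11 unchanged genes, and called no gene in a contrast without change. Other alternatives were no filter or a filter of 50 percent, quantile normalization, the mean of a gene's probe sets, single probe sets, no probe sets that may bind several genes, an offset of 16, array weights, a trended robust variance, replicate number as a block, an adjusted p under 0.1, only the groups compared, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.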

Results

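Whole-tumor RNA was profiled in 12 subcutaneous LLC tumors, in 4 groups of 3. The groups received the control antibody 13C4 (control), the TGF-beta-neutralizing antibody 1D11 (1D11), 13C4 with radiation (radiation), or 1D11 with radiation (1D11_radiation). The design asks what radiation changes in the tumor, what neutralizing TGF-beta changes, and whether 1D11 alters the response to radiation. The series title ties TGF-beta to radiotherapy resistance in lung cancer. In all, 12735 genes were tested. Markers of neighbouring skeletal muscle varied between tumors, with list scores of 1.27 in control replicate 1 and 2.00 in radiation replicate 3 against -1.39 to 0.70 in the other 10. Control replicate 1 also had the lowest array weight, 0.297, the lowest score of p53 target genes, -0.66, and the lowest hypoxia score, -0.44. The first component of the 12 arrays held 27.7% of the variance.

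Radiation under the control antibody (radiation against control) raised single genes such as Cd80, Ms4a4b and Gzmb and lowered others such as Osr2, Pdgfrb and Rgs5. Cd80, a costimulatory ligand of antigen-presenting cells, rose by 1.48 ± 0.15 (log2 change ± SE, n = 3 tumors per group, adjusted p = 0.0071, limma), from 5.36 ± 0.07 (SD) to 6.84 ± 0.18 log2 intensity. Ms4a4b, a membrane protein of lymphocytes, rose by 2.34 ± 0.29 (adjusted p = 0.00806), and Cxcl9, an interferon-induced chemokine that draws T cells, by 2.23 ± 0.47 (adjusted p = 0.0348). Ccl5, a T cell chemokine (1.67 ± 0.24), Klrd1, a natural killer receptor chain (1.66 ± 0.28), and Gzmb, a protease of cytotoxic granules (1.41 ± 0.22), rose at adjusted p from 0.0116 to 0.0189. H2-Aa, an MHC class II chain (1.42 ± 0.28), Fcgr4, an IgG receptor (1.33 ± 0.23), P2ry10 (2.07 ± 0.41) and Erc2 (1.33 ± 0.23) complete the 10 largest rises. Osr2, a zinc-finger transcription factor, changed by -1.72 ± 0.20 (adjusted p = 0.0071). Pdgfrb, the growth factor receptor of pericytes and fibroblasts, changed by -2.05 ± 0.32 (adjusted p = 0.0139), and the matrix proteoglycan Aspn by -2.38 ± 0.47 (adjusted p = 0.0294). The other large falls were Mest (-1.61 ± 0.33), Lrrc17 (-1.58 ± 0.33), Lhx9 (0.355-fold) and Vwf, the endothelial clotting factor (-1.41 ± 0.31). Cdon (-1.34 ± 0.27), Lgalsl (-1.26 ± 0.20) and the pericyte marker Rgs5 (-1.21 ± 0.20) fell as well. Of the TGF-beta genes, Tgfb3 fell by 0.85 ± 0.20 (adjusted p = 0.0491). Tgfb1 (0.28 ± 0.11, adjusted p = 0.211), Tgfb2 (-0.48 ± 0.23), Tgfbr1 (-0.32 ± 0.12), Tgfbr2 (-0.05 ± 0.10) and the TGF-beta-induced inhibitor Smad7 (-0.02 ± 0.10) did not pass. Mdm2, a p53 target, rose by 0.61 ± 0.12 (adjusted p = 0.0294), and Cdkn1a, which encodes the p53-induced cell cycle inhibitor p21, had 0.79 ± 0.27 (adjusted p = 0.151).

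In all, 304 genes were called between radiation and control, 188 higher and 116 lower, 44 of them by more than 2-fold. The count was 179 with the keratinocyte score and 573 with the muscle score as a covariate, 193 with the mean of probe sets, 890 with array weights and 6 with only the 2 groups compared. With quantile normalization 51.6% of the called genes were higher, against 61.8% as deposited. The count was 436, 166 and 204 without control replicates 1, 2 and 3. It was 39, 20 and 403 without radiation replicates 1, 2 and 3. It was 170 to 189 without 1D11 replicate 2, 1D11_radiation replicate 1 or 1D11_radiation replicate 3, and 569 without both control replicate 1 and radiation replicate 3. Cd80, Ms4a4b and Osr2 passed with any single tumor left out. Ccl5, Klrd1, Gzmb and Rgs5 lost the call without radiation replicate 1 or 2, at adjusted p up to 0.0836, and Pdgfrb without radiation replicate 2, at 0.0590. The other named genes lost it without 1 to 10 of the tumors, with no change of sign and adjusted p up to 0.166, for Tgfb3.

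Of 19 measured endothelial genes 18 were lower in irradiated tumors and 6 fell (12 when adjusted over the list alone). Among them were Tek, the angiopoietin receptor (-0.66 ± 0.13), Sox18, an endothelial transcription factor (-0.72 ± 0.14), Egfl7 (-0.50 ± 0.09) and Ecscr (-0.65 ± 0.11). The median change was -0.50 (camera, adjusted p = 7.03e-10, and adjusted p = 0.372 with an estimated correlation). Of 9 pericyte and smooth muscle genes 8 were lower and 3 fell (5 adjusted over the list alone): Rgs5, Mcam (-0.83 ± 0.15) and the proteoglycan Cspg4 (-0.44 ± 0.10). Their median was -0.63 (adjusted p = 0.000237, and adjusted p = 0.131 with an estimated correlation). Among 20 fibroblast genes, Pdgfra (-0.98 ± 0.14) and Pdgfrb fell, both also when adjusted over the list alone, with a median of -0.14 (adjusted p = 0.0452, and adjusted p = 0.752 with an estimated correlation). Collagen and matrix genes had a median of -0.20 with no member called (adjusted p = 0.0370, and adjusted p = 0.770 with an estimated correlation). Their call ended without control replicate 1 (median -0.14), radiation replicate 1 (-0.17) or radiation replicate 2 (-0.13). That of the fibroblast list ended without these or without control replicate 3, 1D11 replicate 2 or 1D11_radiation replicate 2, at medians of -0.16 to -0.10. Without control replicate 1 the pericyte median was -0.355, and without control replicate 2 the matrix median was -0.13 and the fibroblast median -0.25.

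Of 8 measured genes of cytotoxic lymphocytes 7 were higher and 4 rose (6 adjusted over the list alone): Ccl5, Gzmb, Klrd1 and Gzma (1.12 ± 0.26). The median was 0.84 (adjusted p = 2.63e-05, and adjusted p = 0.372 with an estimated correlation). Dendritic cell genes were higher in 9 of 11, with Cd83, a maturation marker, called (1.04 ± 0.17) and 4 members adjusted over the list alone. Their median was 0.34 (adjusted p = 0.000350, and adjusted p = 0.131 with an estimated correlation). MHC class II genes had a median of 0.81 over 8 members, with H2-Aa called and 5 adjusted over the list alone (adjusted p = 0.000569, and adjusted p = 0.459 with an estimated correlation). Of 23 macrophage genes 19 were higher and 3 rose (4 adjusted over the list alone, with 1 lower). Mrc1, the mannose receptor (1.14 ± 0.15), Fcgr1 (0.84 ± 0.13) and Itgam (0.59 ± 0.13) were called, and the list median was 0.32 (adjusted p = 0.000579, and adjusted p = 0.665 with an estimated correlation). Of 9 T cell genes Cd3d (0.69 ± 0.13) rose, also when adjusted over the list alone, at a median of 0.26 (adjusted p = 0.0123, and adjusted p = 0.459 with an estimated correlation). The immune checkpoint list had a median of 0.34 with Cd80 called among 8 members (adjusted p = 0.00984, and adjusted p = 0.565 with an estimated correlation). That call ended without control replicate 1 (0.29, adjusted p = 0.0702). Skeletal muscle markers were higher in the same tumors, 17 of 17 with no member called, at a median of 1.17 (adjusted p = 0.000569, and adjusted p = 0.752 with an estimated correlation). That median was 0.54 without radiation replicate 3 (adjusted p = 0.145). It was 1.99 without control replicate 1 and 0.72 without control replicate 3, and the checkpoint median was 0.19 without radiation replicate 1 and 0.52 without radiation replicate 3.

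Target genes of p53 were higher in 23 of 25 cases, at a median of 0.43 (adjusted p = 5.02e-09, and adjusted p = 0.443 with an estimated correlation). The death receptor gene Tnfrsf10b (0.44 ± 0.08), the nuclease gene Aen (0.43 ± 0.08) and Mdm2 rose, and 18 rose with 1 lower when adjusted over the list alone. The p53 median was 0.30 to 0.54 with any single tumor left out. Mitosis genes (27 of 29 higher, median 0.18, adjusted p = 9.56e-05, and adjusted p = 0.752 with an estimated correlation) had no member called (1 adjusted over the list alone). The mitosis call ended without control replicate 3 (0.07, adjusted p = 0.0652). Hypoxia and glycolysis genes (21 of 24 higher, median 0.23, adjusted p = 0.000612, and adjusted p = 0.752 with an estimated correlation) had none called. The hypoxia median was 0.05 without control replicate 1 (adjusted p = 0.552). Interferon response genes had a median of 0.24 with Cxcl9 called (adjusted p = 0.00161, and adjusted p = 0.752 with an estimated correlation). It was 0.09 without control replicate 3 (adjusted p = 0.213) and 0.23 without radiation replicate 3 (adjusted p = 0.0762). Inflammatory cytokines had a median of 0.48 with Csf1 called (0.48 ± 0.11; adjusted p = 0.00984, and adjusted p = 0.752 with an estimated correlation). It was 0.22 without control replicate 1 (adjusted p = 0.422) and 0.11 without radiation replicate 1 (adjusted p = 0.402). The latter tumor had the highest score of stress and RNA quality genes, 0.44, and a cytokine score of 0.54. The remaining 15 lists were not called. TGF-beta target genes had a median of -0.02 (adjusted p = 0.811), with Timp1 called (0.54 ± 0.12), and DNA repair genes -0.01 (adjusted p = 0.747), where Xrcc4 fell by 0.44 ± 0.10. DNA replication (-0.09, adjusted p = 0.0528), unfolded protein response (0.05), stress response (0.04), B and plasma cell (-0.04), nerve (-0.04), epithelial-mesenchymal transition (0.08) and MHC class I genes (0.07) did not pass. Neither did adipocyte (-0.08), neutrophil (0.01), ribosomal (-0.02), keratinocyte (0.01), oxidative phosphorylation (0.00) and mast cell genes (0.20), with adjusted p from 0.747 to 0.901. With calls kept, the hypoxia median was 0.14 without radiation replicate 1, the interferon median 0.46 without control replicate 2 and the mitosis median 0.32 without control replicate 1.

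**Figure D1:**
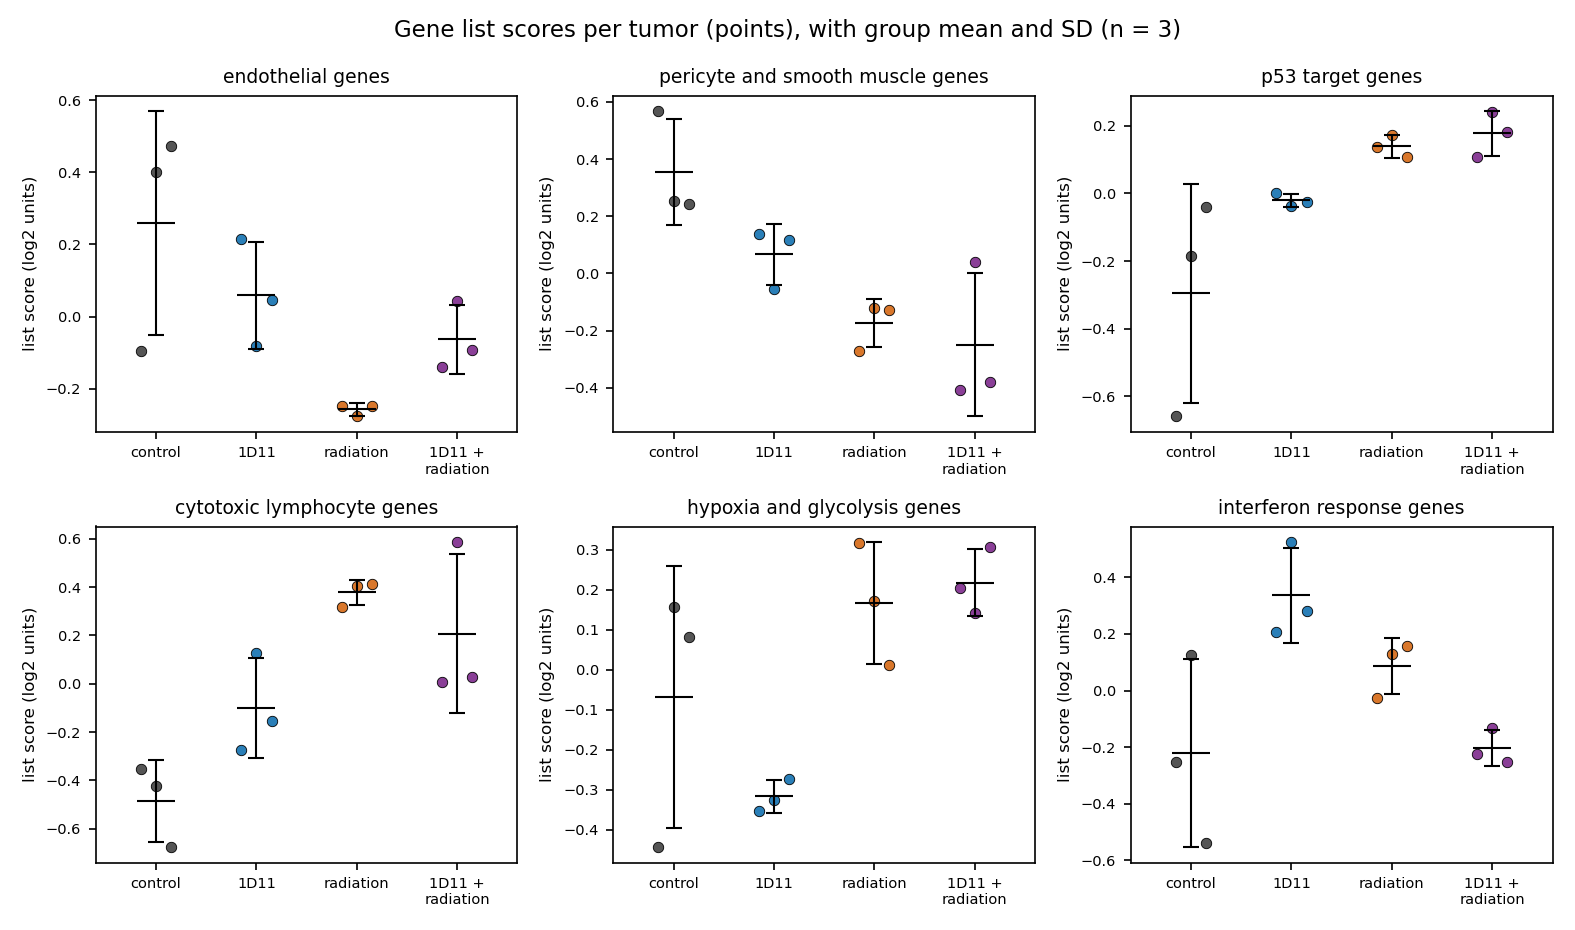
Scores of 6 gene lists per tumor (points; log2 units, mean of the members' centred values) in the 4 groups, with the group mean and SD (bars, n = 3). Radiation tumors lie lowest for endothelial genes, with a mean of -0.26 ± 0.02 against 0.26 ± 0.31 in control tumors, and 1D11 tumors lie highest for interferon genes, with 0.34 ± 0.17.

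Under 1D11, radiation (1D11_radiation against 1D11) changed Aplnr, the apelin receptor of endothelial cells, by -1.66 ± 0.12 (adjusted p = 0.000322) and Osr2 by -1.72 ± 0.20 (adjusted p = 0.0159). The mast cell protease Mcpt4 (-1.59 ± 0.24), Prrg2 (-0.65 ± 0.09), Trio, a GTPase exchange factor (-0.56 ± 0.08), and the guidance cue Ntn1 (-0.52 ± 0.07) fell too, at adjusted p from 0.0364 to 0.0499. Srgap3, a GTPase-activating protein, rose by 0.90 ± 0.11 (adjusted p = 0.0252), the metalloprotease gene Adam8 by 0.67 ± 0.09, the drug transporter gene Abcc1 by 0.60 ± 0.09 and Cystm1 by 0.44 ± 0.06. These were the 10 genes called, of 1979 at an unadjusted p under 0.05. With the replicate block 1 gene was called and with the keratinocyte covariate 2, and of the 10 only Aplnr kept its call (adjusted p = 0.00365 and 0.016). The mean of probe sets called 35 genes, but not Trio (-0.14, adjusted p = 0.393) or Cystm1 (0.23, 0.136). Osr2 (-0.89), Aplnr (-1.025) and Prrg2 (-0.375) were smaller there and kept the call. With array weights the count was 1491. Mdm2 (0.39 ± 0.12, adjusted p = 0.165), Cdkn1a (0.46 ± 0.27), Tgfb1 (0.01 ± 0.11), Tgfb2 (-0.20 ± 0.23), Tgfb3 (-0.59 ± 0.20), Tgfbr1 (0.09 ± 0.12), Tgfbr2 (-0.01 ± 0.10) and Smad7 (0.13 ± 0.10) did not pass. The count was 227 without control replicate 1, and 22 without control replicate 2 or radiation replicate 3. It was 1 to 5 without any 1D11 tumor, radiation replicate 2 or 1D11_radiation replicate 1 or 3. Without control replicate 1 and radiation replicate 3 together it was 419. Aplnr passed with any single tumor left out; Osr2 lost the call without 1D11 replicate 1 or 3 or 1D11_radiation replicate 1 or 3 (adjusted p up to 0.0602). The other 8 genes lost it without 3 to 9 tumors (adjusted p up to 0.156).

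Hypoxia and glycolysis genes were higher in 23 of 24 cases in 1D11_radiation than in 1D11 tumors, with no member called over all genes and 17 higher and 1 lower adjusted over the list alone. Their median was 0.54 (camera, adjusted p = 2.03e-16, and adjusted p = 0.342 with an estimated correlation). P4ha2, a collagen prolyl hydroxylase, had 0.96 ± 0.20 and the glycolytic gene Pgk1 0.37 ± 0.08. Interferon response genes were lower in 27 of 28 cases, at a median of -0.54 (19 adjusted over the list alone; adjusted p = 4.28e-12, and adjusted p = 0.560 with an estimated correlation), with Oasl2 at -0.85 ± 0.18 and Ifit1 at -1.16 ± 0.29. Inflammatory cytokines had a median of 0.67 (2 adjusted over the list alone; adjusted p = 1.88e-07, and adjusted p = 0.604 with an estimated correlation), with Csf2 at 0.78 ± 0.12 and Ccl3 at 1.11 ± 0.31. The score of stress and RNA quality genes was lowest in 1D11 replicates 2 and 3 (-0.23 and -0.24), where cytokine scores were -0.62 and -0.52. The stress list was not called (median 0.07, adjusted p = 0.106). Mast cell genes had a median of -1.59 with Mcpt4 called and 6 lower and 1 higher adjusted over the list alone (adjusted p = 5.87e-05, and adjusted p = 0.342 with an estimated correlation). Keratinocyte markers moved with them, lower in 8 of 8 at a median of -0.96 (4 adjusted over the list alone; adjusted p = 0.000403, and adjusted p = 0.638 with an estimated correlation). Adipocyte genes had -0.65 (3 adjusted over the list alone; adjusted p = 0.00912, and adjusted p = 0.560 with an estimated correlation), or -0.54 without 1D11 replicate 3 (adjusted p = 0.0627). p53 targets had a median of 0.17 (1 lower adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.644 with an estimated correlation). Neutrophil, cytotoxic lymphocyte, MHC class I, fibroblast and macrophage genes were also called, at medians of 0.27, 0.26, -0.11, -0.31 and -0.22 (adjusted p from 0.0101 to 0.0380, and adjusted p from 0.644 to 0.700 with an estimated correlation). All 5 calls ended without 1D11 replicate 3 (adjusted p from 0.0627 to 0.316), some without 1D11 replicate 2 or 1D11_radiation replicate 2 (0.0611 to 0.206), and those of cytotoxic and fibroblast genes without 1D11 replicate 1 (0.118 and 0.0667). For fibroblast or macrophage genes, 1D11_radiation replicate 1 or 3 (0.169 to 0.403), control replicate 1 (0.0579) or radiation replicate 3 (0.0505) also ended the call. With the keratinocyte score as a covariate adipocyte, cytotoxic, MHC class I, fibroblast and macrophage genes lost the call (adjusted p from 0.0662 to 0.461), and the last 2 also with the muscle score (0.115 and 0.0758). Inflammatory cytokines were at 0.34 without 1D11 replicate 2 and 0.41 without 1D11 replicate 3, and keratinocyte markers at -0.47 without 1D11 replicate 3. Cytotoxic genes were at 0.10 and 0.43 without 1D11 replicates 1 and 2, and at 0.41 and 0.07 without 1D11_radiation replicates 1 and 2. Neutrophil genes were at 0.44 and 0.16 without 1D11 replicates 1 and 2, and fibroblast genes at -0.51 and -0.10 without 1D11_radiation replicates 2 and 3. Macrophage genes were at -0.135 without 1D11 replicate 3, and at -0.09, -0.35 and -0.15 without 1D11_radiation replicates 1, 2 and 3.

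Over both antibodies, the 6 irradiated tumors were set against the 6 that were not. Aplnr (-1.27 ± 0.09, adjusted p = 0.000146), Osr2 (-1.72 ± 0.14, adjusted p = 0.000475), Id3, a helix-loop-helix inhibitor (-1.03 ± 0.11), the nuclear receptor gene Nr2f1 (-0.67 ± 0.07) and Prrg2 (-0.62 ± 0.06) fell. Cd80 (1.11 ± 0.11, adjusted p = 0.00121), Adam8 (0.70 ± 0.07), Srgap3 (0.76 ± 0.08), Abcc1 (0.57 ± 0.06) and Cystm1 (0.42 ± 0.05) rose, with adjusted p no higher than 0.00172 for any of the 10. Mdm2 rose by 0.50 ± 0.09 (adjusted p = 0.00921), Tgfb3 changed by -0.72 ± 0.14 (adjusted p = 0.0134), and all 12 of these genes passed with any single tumor left out. Cdkn1a (0.63 ± 0.19, adjusted p = 0.0720), Tgfb1 (0.15 ± 0.08), Tgfb2 (-0.34 ± 0.16), Tgfbr1 (-0.11 ± 0.09), Tgfbr2 (-0.03 ± 0.07) and Smad7 (0.06 ± 0.07) did not pass. In all, 925 genes were called, 432 higher and 493 lower, and 32 by more than 2-fold. With the keratinocyte score as a covariate 300 were called, 281 of them among the 925, and with array weights 2176. The count was 407 without radiation replicate 1, 442 without 1D11_radiation replicate 3, and 449 without 1D11 replicate 2. It was 543 to 613 without radiation replicate 2, 1D11_radiation replicate 1, 1D11 replicate 3 or 1D11 replicate 1, and 1410 without control replicate 1 and radiation replicate 3 together.

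**Figure D2:**
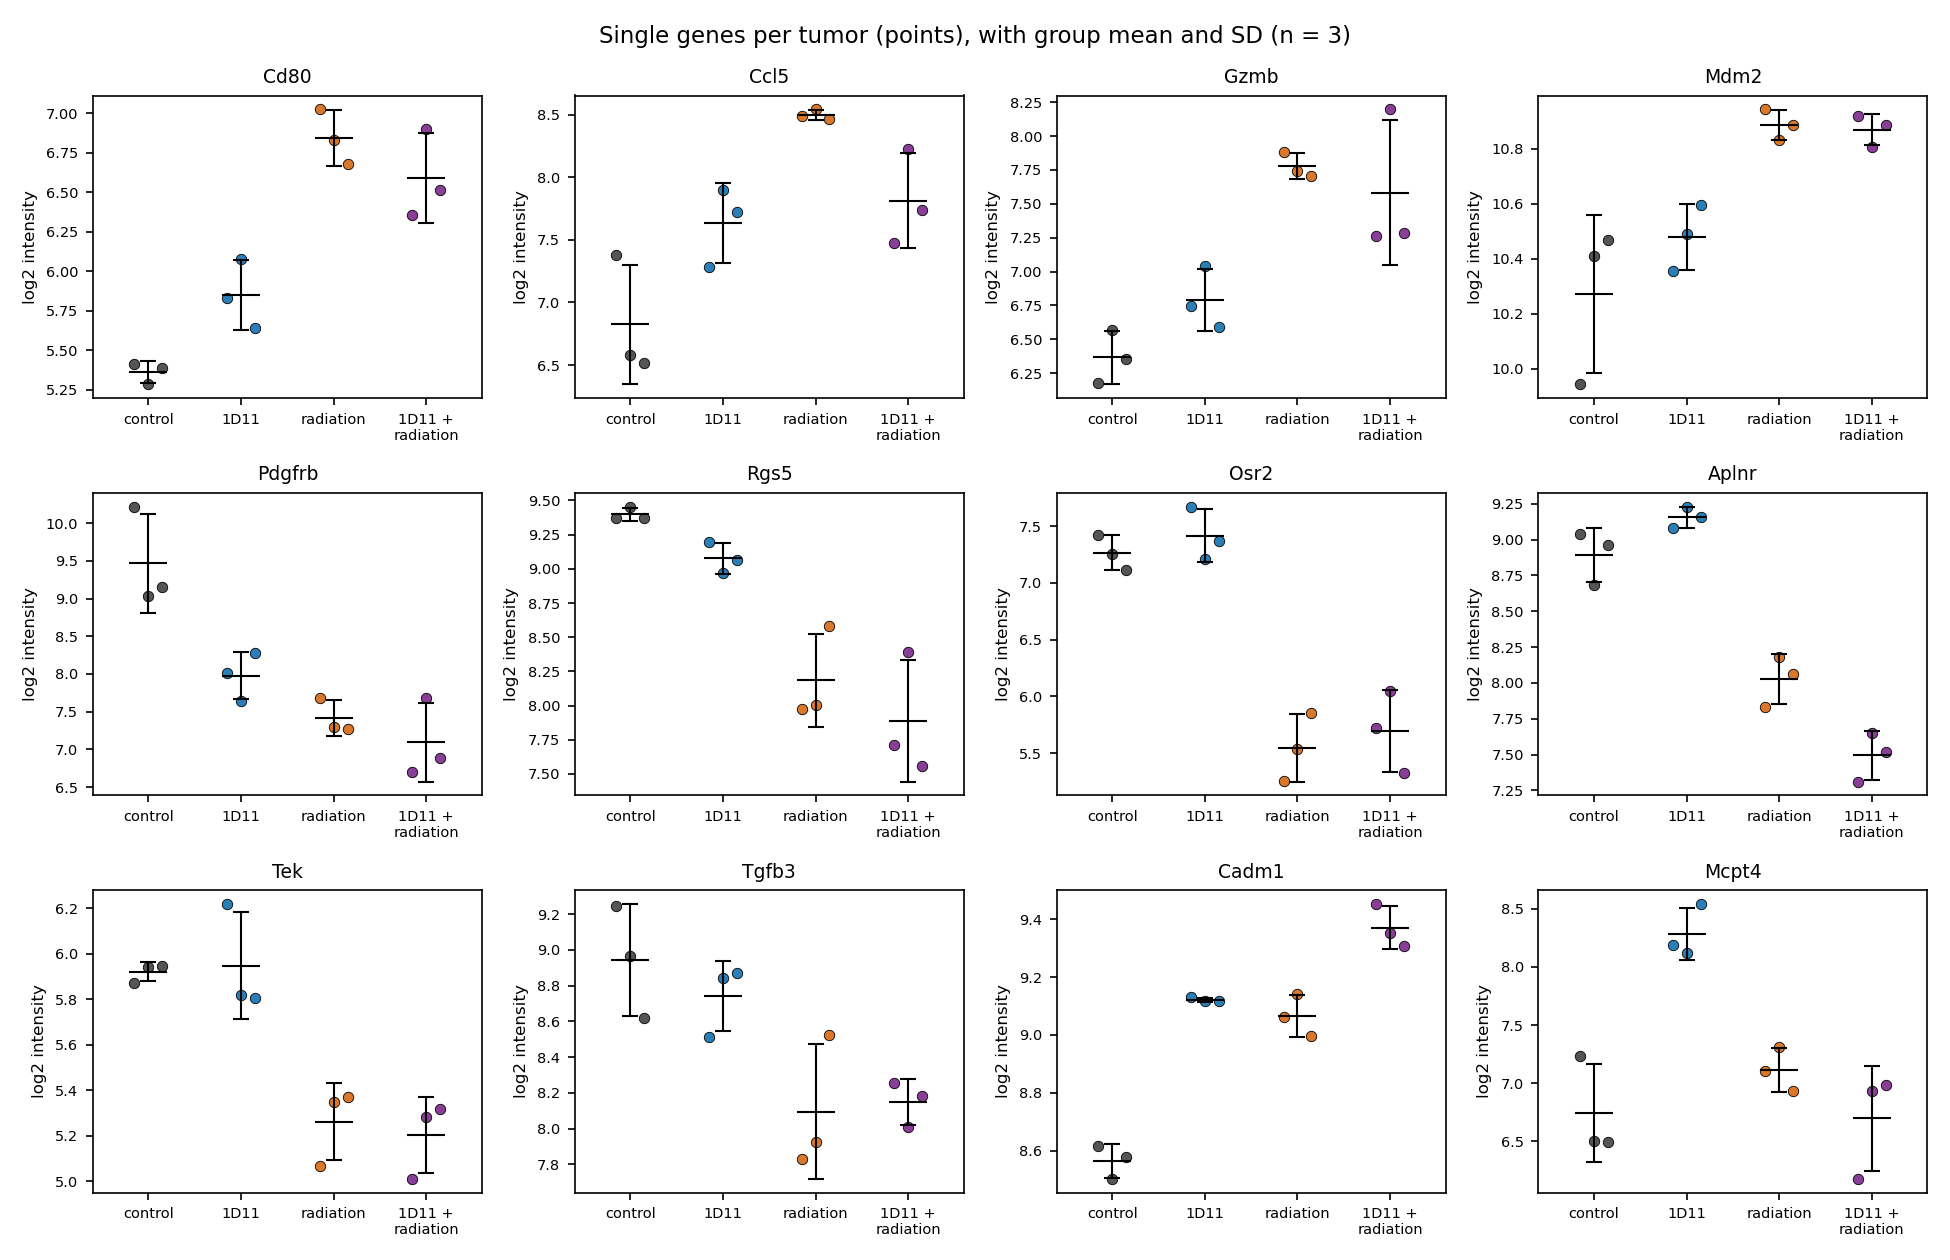
Log2 intensity of 12 genes per tumor (points) in the 4 groups, with the group mean and SD (bars, n = 3). For Osr2 and Tek each irradiated tumor lies below each tumor that was not irradiated, and Cadm1 is lowest in control tumors, at 8.57 ± 0.06.

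Of 24 hypoxia and glycolysis genes, 11 rose with radiation over both antibodies (18 higher and 1 lower adjusted over the list alone), at a median of 0.39 (adjusted p = 7.45e-11, and adjusted p = 0.386 with an estimated correlation). Pgk1 (0.30 ± 0.06), Pgm1 (0.44 ± 0.09), Pfkfb3 (0.52 ± 0.12) and the hexokinase gene Hk2 (0.36 ± 0.08) were among them. Of 25 p53 targets 5 rose and Sesn1 (-0.44 ± 0.08) fell, at a median of 0.33 (18 higher and 1 lower adjusted over the list alone; adjusted p = 5.52e-08, and adjusted p = 0.386 with an estimated correlation), with the cell death gene Pmaip1 at 1.26 ± 0.25. Endothelial genes had a median of -0.33 with 5 called, Tek at -0.70 ± 0.09 (8 adjusted over the list alone; adjusted p = 8.25e-06, and adjusted p = 0.484 with an estimated correlation). Pericyte genes had -0.41 with Rgs5 (-1.20 ± 0.15) and Mcam (-0.46 ± 0.10) called (5 adjusted over the list alone; adjusted p = 0.00163, and adjusted p = 0.386 with an estimated correlation). Cytotoxic lymphocyte genes had 0.65 with Gzmb (1.10 ± 0.16), Ccl5 (0.93 ± 0.17), Gzma and Klrd1 called (5 adjusted over the list alone; adjusted p = 4.02e-05, and adjusted p = 0.386 with an estimated correlation). Inflammatory cytokines had 0.53 with Csf2, Csf1, Ccl8 and Ccl3 called (5 adjusted over the list alone; adjusted p = 8.25e-06, and adjusted p = 0.491 with an estimated correlation). Stress and RNA quality genes had 0.11 beside them and were not called (adjusted p = 0.110). Pdgfra (-0.92 ± 0.10), Pdgfrb (-1.47 ± 0.23) and Islr fell among fibroblast genes, and Col6a1 (-0.79 ± 0.20), Col6a2 (-0.97 ± 0.24) and Col6a3, chains of collagen VI, among matrix genes. Both lists were called, at medians of -0.18 (adjusted p = 0.0214 and 0.0290, and adjusted p = 0.659 and 0.692 with an estimated correlation). Mast cell genes (-0.61, with Kit called), T cell (0.12), checkpoint (0.15), dendritic (0.15), MHC class II (0.35) and mitosis genes (0.10) were called too (adjusted p from 0.00307 to 0.0305, and adjusted p from 0.386 to 0.692 with an estimated correlation). Interferon (-0.16), DNA replication (-0.11) and keratinocyte genes (-0.44) were lower (adjusted p from 0.0299 to 0.0383, and adjusted p from 0.692 to 0.696 with an estimated correlation). Of these 11 lists, all but mast, T cell and dendritic genes lost the call without at least 1 tumor. Mitosis (adjusted p = 0.0768) and checkpoint genes (0.0581) lost it without control replicate 3, and fibroblast and matrix genes without radiation replicate 2 or 1D11_radiation replicate 1 or 3 (0.0515 to 0.138). Interferon genes lost it without control replicate 2, 1D11 replicate 2 or radiation replicate 1 (0.116 to 0.409), and DNA replication genes without control replicate 1, 1D11 replicate 1, radiation replicate 3 or 1D11_radiation replicate 2 (0.0520 to 0.332). MHC class II genes lost it without control replicate 3, 1D11 replicate 1, radiation replicate 2 or 1D11_radiation replicate 2 (0.0768 to 0.0924). Keratinocyte genes lost it without any control tumor, 1D11 replicate 3, radiation replicate 2 or 3, or 1D11_radiation replicate 1 or 3 (0.0514 to 0.216). Fibroblast and matrix genes also lost it with the keratinocyte score as a covariate (0.0624 and 0.0631), and MHC class II genes with the muscle score (0.0508). In exact permutation tests of the list scores (400 relabelings within antibody, smallest possible p = 0.005), p53 targets differed by 0.32 (p = 0.005), endothelial genes by -0.32 and pericyte genes by -0.42 (p = 0.01 each). In the same exact test cytotoxic genes differed by 0.59 (p = 0.015) and hypoxia genes by 0.39 (p = 0.02). None of the 31 lists passed after adjustment there, with a smallest adjusted p = 0.093. Medians moved for checkpoint genes (0.10, 0.28 and 0.09 without radiation replicate 1, radiation replicate 3 or 1D11_radiation replicate 2), keratinocyte genes (-0.66 and -0.19 without 1D11 replicates 2 and 3) and fibroblast genes (-0.34 and -0.10 without 1D11_radiation replicates 2 and 3). Matrix genes were at -0.11 without 1D11_radiation replicate 3, dendritic genes at 0.22 without control replicate 2, and interferon genes at -0.09 without control replicate 2 or radiation replicate 1. DNA replication genes were at -0.06 without control replicate 1, and mitosis genes at 0.15 and 0.05 without control replicates 1 and 3.

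Among tumors without radiation, 1D11 (1D11 against control) raised Cadm1, a cell adhesion molecule, by 0.56 ± 0.06 (adjusted p = 0.0366, limma; chromosome 9, 47530170 to 47862280 in GRCm38) and Ccl6, a myeloid chemokine, by 0.87 ± 0.11 (adjusted p = 0.0474; chromosome 11, 83587886 to 83593087). Both were higher in all 3 1D11 tumors than in all 3 control tumors. These were the only 2 genes called, of 1800 at an unadjusted p under 0.05. No gene passed in the other direction, and Tgfb1 (0.16 ± 0.11), Tgfb2 (-0.37 ± 0.23), Tgfb3 (-0.20 ± 0.20), Tgfbr1 (-0.34 ± 0.12), Tgfbr2 (0.12 ± 0.10), Smad7 (-0.26 ± 0.10), Mdm2 (0.21 ± 0.12) and Cdkn1a (0.30 ± 0.27) had adjusted p of 0.271 or more. With the keratinocyte score as a covariate both calls ended, Cadm1 at 0.555 (adjusted p = 0.315) and Ccl6 at 0.81 (adjusted p = 0.454). They also ended with quantile normalization (adjusted p = 0.0641 for both), the mean of a gene's probe sets (0.116 and 0.0646), the replicate block (0.0725 for both), single probe sets and only the 2 groups compared. Both calls were lost without control replicate 3, any 1D11 tumor, radiation replicate 1, radiation replicate 2 or 1D11_radiation replicate 1 (adjusted p up to 0.285). The count was 21 without control replicate 1 or control replicate 2, 5 without radiation replicate 3, 0 to 3 without any other tumor, and 59 without control replicate 1 and radiation replicate 3 together.

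Interferon response genes were higher in 28 of 28 cases in 1D11 than in control tumors, at a median of 0.56, with none called over all genes and 16 adjusted over the list alone (adjusted p = 8.29e-10, and adjusted p = 0.485 with an estimated correlation). Gbp2, an interferon-induced GTPase, had 0.91 ± 0.19 (adjusted p = 0.127) and Cxcl9 2.07 ± 0.47 (adjusted p = 0.136). Mast cell, basophil and eosinophil genes were higher in 7 of 7 at a median of 1.52, with 5 adjusted over the list alone (adjusted p = 5.97e-05, and adjusted p = 0.233 with an estimated correlation). The mast cell proteases Mcpt4 and Cma1 had 1.54 ± 0.24 and 1.56 ± 0.29. Keratinocyte markers were higher in the same group, 8 of 8 at a median of 0.89 (2 adjusted over the list alone; adjusted p = 0.000576, and adjusted p = 0.485 with an estimated correlation). Their score was 2.18 in 1D11 replicate 3, 0.75 in replicate 1 and -0.33 in replicate 2. Nerve marker scores were 0.12 ± 0.11 (SD) in 1D11 and -0.22 ± 0.16 in control tumors, and that list was not called (median 0.18, adjusted p = 0.213). TGF-beta target genes were lower in 15 of 23 cases at a median of -0.26 (1 adjusted over the list alone; adjusted p = 0.00111, and adjusted p = 0.250 with an estimated correlation). Ccn2, a matricellular TGF-beta target, had -1.16 ± 0.24 (adjusted p = 0.127), Bhlhe40 -0.51 ± 0.15, Itgb5 -0.62 ± 0.20 and Snai2 0.60 ± 0.18. Hypoxia and glycolysis genes had a median of -0.25 (adjusted p = 3.83e-06, and adjusted p = 0.485 with an estimated correlation), and pericyte genes had -0.32 (1 adjusted over the list alone; adjusted p = 0.00111, and adjusted p = 0.233 with an estimated correlation). Macrophage genes had 0.27 (4 higher and 1 lower adjusted over the list alone; adjusted p = 0.00111, and adjusted p = 0.540 with an estimated correlation) and endothelial genes -0.18 (adjusted p = 3.76e-05, and adjusted p = 0.485 with an estimated correlation). p53 targets had 0.28 (adjusted p = 4.32e-05, and adjusted p = 0.485 with an estimated correlation), or 0.11 without control replicate 1 (adjusted p = 0.174). Mitosis, MHC class I, MHC class II, cytotoxic lymphocyte and unfolded protein response genes were called at medians of 0.14, 0.13, 0.56, 0.29 and -0.06 (adjusted p from 0.00357 to 0.0462, and adjusted p from 0.485 to 0.763 with an estimated correlation). Control replicate 3 ended the first 4 of these calls (adjusted p from 0.177 to 0.653). The unfolded protein response lost its call without control replicate 1 or 2 or 1D11 replicate 1 (0.118 to 0.133). Control replicate 2 (0.0544 and 0.0748), 1D11 replicate 2 (0.164 to 0.298), 1D11 replicate 3 (0.133 and 0.189), radiation replicate 2 (0.0546) and radiation replicate 3 (0.0694) each ended 1 to 3 of the others. MHC class I and II genes lost the call with the muscle or keratinocyte score as a covariate, cytotoxic genes with the first and unfolded protein response genes with the second (adjusted p from 0.0527 to 0.116). TGF-beta target genes were at -0.12 without control replicate 1 (adjusted p = 0.00847). Hypoxia genes were at -0.38, -0.11 and -0.14 without control replicates 1, 2 and 3. Endothelial genes were at -0.34, -0.11 and -0.07 without these 3 tumors, and at -0.29 and -0.11 without 1D11 replicates 1 and 2. Keratinocyte markers were at 0.43 without 1D11 replicate 3, and mitosis genes at 0.26 and 0.03 without control replicates 1 and 3. MHC class I genes were at 0.23, 0.06 and 0.21 without control replicate 2, control replicate 3 or 1D11 replicate 1, and cytotoxic genes at 0.19 without 1D11 replicate 2. Unfolded protein response genes were at -0.04 and -0.11 without control replicates 1 and 3, and at -0.02, -0.09 and -0.04 without 1D11 replicates 1, 2 and 3.

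Among irradiated tumors, 1D11 (1D11_radiation against radiation) changed no gene at the threshold. limma called 0 of 12735 genes, with 688 at an unadjusted p under 0.05 where 637 would be expected by chance, and a smallest adjusted p = 0.84. Among the smallest unadjusted p in each direction were those of the growth factor gene Hgf (0.33 ± 0.06), the Wnt inhibitor gene Frzb (0.81 ± 0.15), Mpdz (0.51 ± 0.10). In the other direction were the fractalkine receptor gene Cx3cr1 (-0.87 ± 0.16), Slamf7 (-0.48 ± 0.10) and the innate receptor gene Tlr2 (-0.62 ± 0.14), all at adjusted p = 0.84. Tgfb1 (-0.11 ± 0.11), Tgfb2 (-0.09 ± 0.23), Tgfb3 (0.05 ± 0.20), Tgfbr1 (0.08 ± 0.12), Tgfbr2 (0.15 ± 0.10), Smad7 (-0.11 ± 0.10), Mdm2 (-0.02 ± 0.12) and Cdkn1a (-0.04 ± 0.27) did not pass. Interferon response genes were lower in 26 of 28 cases at a median of -0.26 (1 adjusted over the list alone; adjusted p = 3.49e-08, and adjusted p = 0.502 with an estimated correlation), with Oasl1 at -0.43 ± 0.10. Neutrophil genes were higher in 13 of 14 at a median of 0.49 (1 adjusted over the list alone, Mmp8 at 0.80 ± 0.22; adjusted p = 6.11e-05, and adjusted p = 0.502 with an estimated correlation). Dendritic cell genes had -0.19 (adjusted p = 0.000203, and adjusted p = 0.197 with an estimated correlation) and MHC class II genes -0.35 (adjusted p = 0.00105, and adjusted p = 0.502 with an estimated correlation), or -0.20 without radiation replicate 2 (adjusted p = 0.0538). TGF-beta targets were lower in 18 of 23 at a median of -0.11 (adjusted p = 0.0163, and adjusted p = 0.502 with an estimated correlation), and -0.06 without radiation replicate 1 (adjusted p = 0.380). Tgfb1i1 had -0.59 ± 0.15 and Pmepa1, an inhibitor of TGF-beta signalling, -0.87 ± 0.28. Skeletal muscle markers differed most, lower in 17 of 17 at a median of -1.56 with none called (adjusted p = 2.43e-10, and adjusted p = 0.502 with an estimated correlation). Macrophage (-0.19), unfolded protein response (-0.09), endothelial (0.19), inflammatory cytokine (0.13), adipocyte (-0.23) and MHC class I genes (-0.11) were also called (adjusted p from 0.000523 to 0.0374, and adjusted p from 0.502 to 0.795 with an estimated correlation). All 6 calls but the endothelial one ended without 1 tumor. For the macrophage median that was 1D11_radiation replicate 1 (-0.07), and for the unfolded protein response radiation replicate 1 (adjusted p = 0.0638). The other 3 ended without 1D11_radiation replicate 1 (0.124 to 0.261), 1D11_radiation replicate 2 (0.141), 1D11_radiation replicate 3 (0.0503 and 0.125), radiation replicate 2 (0.110 to 0.191) or radiation replicate 3 (0.130 to 0.458). With the muscle score as a covariate the inflammatory cytokine median changed direction, to -0.12 (adjusted p = 0.0252). The calls of endothelial (0.04, adjusted p = 0.606), adipocyte (0.03, 0.606), macrophage (-0.10, 0.0844) and MHC class I genes (-0.09, 0.0993) ended with it. Those of adipocyte and MHC class I genes also ended with the keratinocyte score (0.0504 each). Neutrophil genes were at 0.30 and MHC class II genes at -0.59 without radiation replicate 3, MHC class I genes at -0.06 without radiation replicate 2, and dendritic genes at -0.34 without 1D11_radiation replicate 2. Adipocyte genes were at -0.375 and -0.41 without radiation replicate 1 or 1D11_radiation replicate 2. Inflammatory cytokines were at 0.25, 0.26 and 0.03 without radiation replicates 1, 2 and 3, and at 0.21 without 1D11_radiation replicate 2.

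**Figure D3:**
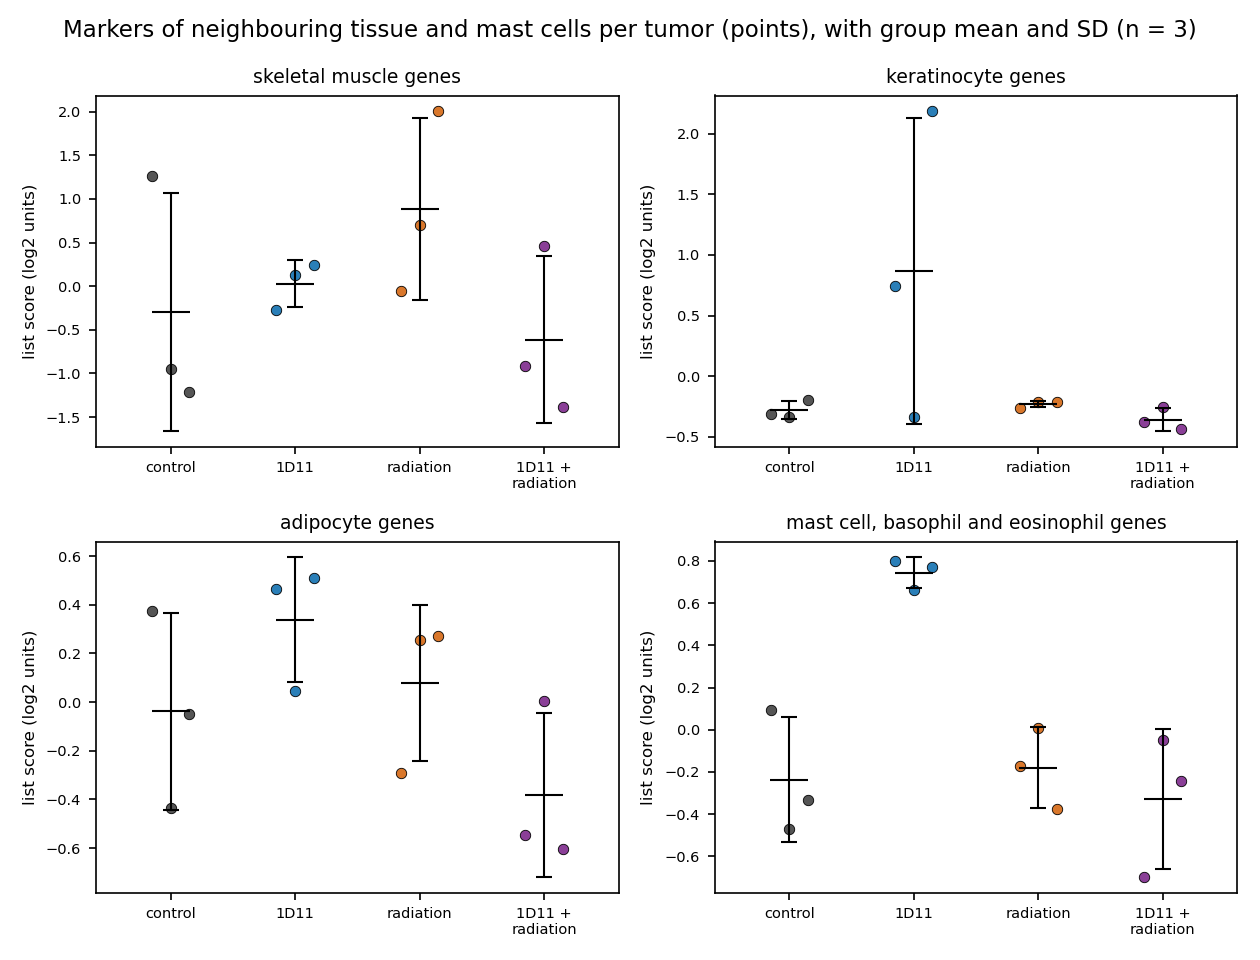
Scores of skeletal muscle, keratinocyte, adipocyte and mast cell lists per tumor (points; log2 units) in the 4 groups, with the group mean and SD (bars, n = 3). Mast cell scores of the 3 1D11 tumors lie between 0.66 and 0.80, above the 9 others, while their keratinocyte scores run from -0.33 to 2.18.

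Over both radiation states, the 6 tumors with 1D11 were set against the 6 with 13C4. Cadm1 rose by 0.43 ± 0.05 (adjusted p = 0.0148) and was the only gene called, of 1591 at an unadjusted p under 0.05. Ccl6 (0.56 ± 0.08, adjusted p = 0.0747), Mpdz (0.49 ± 0.07), Lrba (0.44 ± 0.07) and Mrc1 (0.62 ± 0.11) were next among the rises and did not pass. Among the falls Cx3cr1 (-0.88 ± 0.12, adjusted p = 0.0616), Gpr179 (-0.25 ± 0.05), Sema3f (-0.35 ± 0.07), the heat shock gene Hspa1b (-0.72 ± 0.15) and Stxbp5l (-0.30 ± 0.06) were first and did not pass. Tgfb1 (0.03 ± 0.08), Tgfb2 (-0.23 ± 0.16), Tgfb3 (-0.07 ± 0.14), Tgfbr1 (-0.13 ± 0.09), Tgfbr2 (0.13 ± 0.07), Smad7 (-0.18 ± 0.07), Mdm2 (0.10 ± 0.09) and Cdkn1a (0.13 ± 0.19) had adjusted p of 0.330 or more. TGF-beta target genes were lower in 17 of 23 cases at a median of -0.12 (2 adjusted over the list alone; adjusted p = 0.000566, and adjusted p = 0.319 with an estimated correlation), with Tgfb1i1 at -0.44 ± 0.11 and Pmepa1 at -0.72 ± 0.20. Their mean score differed by -0.15 in an exact permutation test over 400 relabelings within radiation state (p = 0.015, adjusted p = 0.232 over 31 lists). In the same exact permutation test nerve markers differed by 0.235 (p = 0.015), unfolded protein response genes by -0.09 (p = 0.025) and neutrophil genes by 0.37 (p = 0.045), none passing after adjustment. By camera nerve markers were not called (median 0.09, adjusted p = 0.259). Mast cell genes had a median of 0.50 (adjusted p = 0.00301, and adjusted p = 0.319 with an estimated correlation), neutrophil genes 0.45 (adjusted p = 0.00562, and adjusted p = 0.905 with an estimated correlation) and pericyte genes -0.22 (adjusted p = 0.00762, and adjusted p = 0.319 with an estimated correlation). Skeletal muscle markers had -0.63 in the same comparison (adjusted p = 0.000710, and adjusted p = 0.905 with an estimated correlation), or -0.23 without control replicate 1 (adjusted p = 0.0554). The Cadm1 call ended with the replicate block (adjusted p = 0.091), the keratinocyte score as a covariate (0.140) and the mean of a gene's probe sets (0.277), with 0 genes called in each. It was also lost without 1D11 replicate 1 or 3 or 1D11_radiation replicate 1 or 2 (adjusted p up to 0.0869), and neutrophil genes were at 0.22 without 1D11 replicate 1 (adjusted p = 0.0776). The gene count was 0 to 3 without any single tumor. Unfolded protein response (-0.08), p53 target (0.18), hypoxia (-0.06) and keratinocyte genes (0.39) were called too (adjusted p from 0.00108 to 0.0372, and adjusted p from 0.319 to 0.905 with an estimated correlation). With the muscle score as a covariate the p53 median was 0.09 (adjusted p = 0.0713). Without control replicate 1 it was 0.06 (adjusted p = 0.177), and without control replicate 2 the hypoxia median was -0.01 (0.155). Hypoxia genes also lost the call without control replicate 3 (0.108) or radiation replicate 1 (0.0641). Keratinocyte genes lost it without any control tumor, radiation replicate 1 or 2, 1D11_radiation replicate 2 (0.0512 to 0.137) or 1D11 replicate 3, where the median was 0.15 (0.347). Medians also moved for hypoxia genes (-0.17, -0.04 and -0.12 without control replicate 1, radiation replicate 1 or radiation replicate 3), pericyte genes (-0.13 without 1D11_radiation replicate 3), skeletal muscle markers (-0.29 and -0.37 without radiation replicate 3 or 1D11_radiation replicate 3) and keratinocyte genes (0.66 without 1D11 replicate 2).

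Tumors with both treatments differed from control tumors (1D11_radiation against control) in 299 genes, 218 higher and 81 lower, 36 by more than 2-fold. Aplnr (-1.40 ± 0.12, adjusted p = 0.000954), Cx3cr1, a macrophage and microglia receptor (-1.52 ± 0.16, adjusted p = 0.00465), Osr2 (-1.57 ± 0.20), Pdgfrb (-2.37 ± 0.32) and Rgs5 (-1.51 ± 0.20) fell. So did Pmepa1 (-1.84 ± 0.28, adjusted p = 0.0164), Aspn (-2.14 ± 0.47), Lhx9 (-1.22 ± 0.26), Lgalsl (-1.17 ± 0.20) and Ppm1e (-1.14 ± 0.21). Mrc1 (1.32 ± 0.15, adjusted p = 0.00717), the cytochrome gene Cyp2f2 (2.12 ± 0.30, adjusted p = 0.0111), the chemokine genes Ppbp (2.20 ± 0.40), Cxcl9 (2.20 ± 0.47) and Ccl3 (1.64 ± 0.31) rose. Other rises were Cp, which encodes ceruloplasmin (1.78 ± 0.36), Hoatz (2.82-fold), Ephx1 (1.37 ± 0.28), Npl (1.28 ± 0.23) and Ms4a4b (1.27 ± 0.29). Mdm2 rose by 0.60 ± 0.12 (adjusted p = 0.0363); Tgfb3 (-0.79 ± 0.20, adjusted p = 0.0579), Tgfb1 (0.17 ± 0.11), Tgfb2 (-0.56 ± 0.23), Tgfbr1 (-0.24 ± 0.12), Tgfbr2 (0.10 ± 0.10), Smad7 (-0.13 ± 0.10) and Cdkn1a (0.76 ± 0.27, adjusted p = 0.144) did not pass. Target genes of p53 had a median of 0.48 with 3 members called (18 adjusted over the list alone; adjusted p = 1.3e-08, and adjusted p = 0.678 with an estimated correlation). Pericyte genes had -0.49 with Rgs5 and Cspg4 (-0.49 ± 0.10) called (5 adjusted over the list alone; adjusted p = 0.000133, and adjusted p = 0.189 with an estimated correlation). Endothelial genes had -0.34 with Tek called (4 adjusted over the list alone; adjusted p = 4.54e-05, and adjusted p = 0.678 with an estimated correlation). Cytotoxic lymphocyte genes had 0.74 with Gzmb (1.22 ± 0.22) and Gzma called (4 adjusted over the list alone; adjusted p = 0.000461, and adjusted p = 0.678 with an estimated correlation). Inflammatory cytokines had 0.64 with Ccl3 and Csf2 called (4 adjusted over the list alone; adjusted p = 0.000118, and adjusted p = 0.678 with an estimated correlation). Neutrophil genes had 0.52 (3 adjusted over the list alone; adjusted p = 0.00310, and adjusted p = 0.678 with an estimated correlation). Hypoxia (0.23), mitosis (0.13), fibroblast (-0.20) and matrix genes (-0.19) were called as well (adjusted p from 0.000381 to 0.0102, and adjusted p from 0.678 to 0.694 with an estimated correlation). Hypoxia genes were at 0.11 without control replicate 1 (adjusted p = 0.171), mitosis genes at 0.01 without control replicate 3 (0.298), and fibroblast and matrix genes at -0.17 to -0.06 without 1D11_radiation replicate 1 or 3 (0.0575 to 0.179). The gene count was 57, 78 and 17 without 1D11_radiation replicates 1, 2 and 3. It was 151 to 193 without control replicate 1, any 1D11 tumor, radiation replicate 1 or radiation replicate 2, and 341 without control replicate 1 and radiation replicate 3 together. Aplnr, Cx3cr1, Cyp2f2, Mrc1 and Osr2 passed with any single tumor left out. Pdgfrb and Rgs5 lost the call without 1D11_radiation replicate 3 (adjusted p = 0.0501 for both), and Pmepa1, Mdm2 and the other large changes without 2 to 10 tumors (adjusted p up to 0.137). The count was 85 with the replicate block, 163 with the keratinocyte score as a covariate, 178 without the filter, 923 with array weights and 1 with only the 2 groups compared. With quantile normalization 52.5% of the called genes were higher, against 72.9% as deposited. Without control replicate 1 the p53 median was 0.30, that of inflammatory cytokines 0.34 and that of mitosis genes 0.26. Endothelial genes were at -0.19 without control replicate 3, and fibroblast and matrix genes at -0.37 and -0.34 without 1D11_radiation replicate 2.

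Whether 1D11 alters the effect of radiation was tested by the interaction. limma called 0 genes, with 952 at an unadjusted p under 0.05 and a smallest adjusted p = 0.265. The smallest unadjusted p of negative interactions belonged to Stat4, a T cell transcription factor (-0.75 ± 0.12), Fcgr1, an IgG receptor of macrophages (-1.20 ± 0.19), Cd83 (-1.45 ± 0.24), Mcpt4 (-1.96 ± 0.34) and Slco3a1 (-0.53 ± 0.10). Of positive interactions they belonged to Hgf (0.48 ± 0.08), Frzb (1.21 ± 0.22), Rnf144a (0.76 ± 0.14), Rhd (0.44 ± 0.09) and Plcxd1 (0.68 ± 0.15), none of which passed. Tgfb1 (-0.27 ± 0.16), Tgfb2 (0.28 ± 0.32), Tgfb3 (0.26 ± 0.28), Tgfbr1 (0.41 ± 0.18), Tgfbr2 (0.03 ± 0.15), Smad7 (0.15 ± 0.14), Mdm2 (-0.22 ± 0.17) and Cdkn1a (-0.33 ± 0.38) had adjusted p of 0.627 or more. Of 31 lists, 17 were called by camera and none with an estimated correlation (smallest adjusted p = 0.260). Interferon response genes had negative interactions in 28 of 28 cases, at a median of -0.85 (19 adjusted over the list alone; adjusted p = 4.19e-19, and adjusted p = 0.279 with an estimated correlation). Radiation moved them by a median of 0.24 under 13C4 and by -0.54 under 1D11. The gene count was 122 with array weights, 21 without control replicate 1, 1 or 2 without 1D11 replicate 2, radiation replicate 3 or 1D11_radiation replicate 3, and 20 without control replicate 1 and radiation replicate 3 together.

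Across genes, the effects of radiation without and with 1D11 correlated at r = 0.389 (Spearman's rho 0.394), and at 0.198 without control replicate 1; genes are not independent replicates, and no p is given. Of the 304 genes called between radiation and control, 270 (88.8%) had the same sign under 1D11, against 63.2% of all genes, and 7 were called in both. The effects of 1D11 without and with radiation correlated at r = 0.025 (rho 0.157), from -0.22 without control replicate 1 to 0.16 without control replicate 3.

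**Figure D4:**
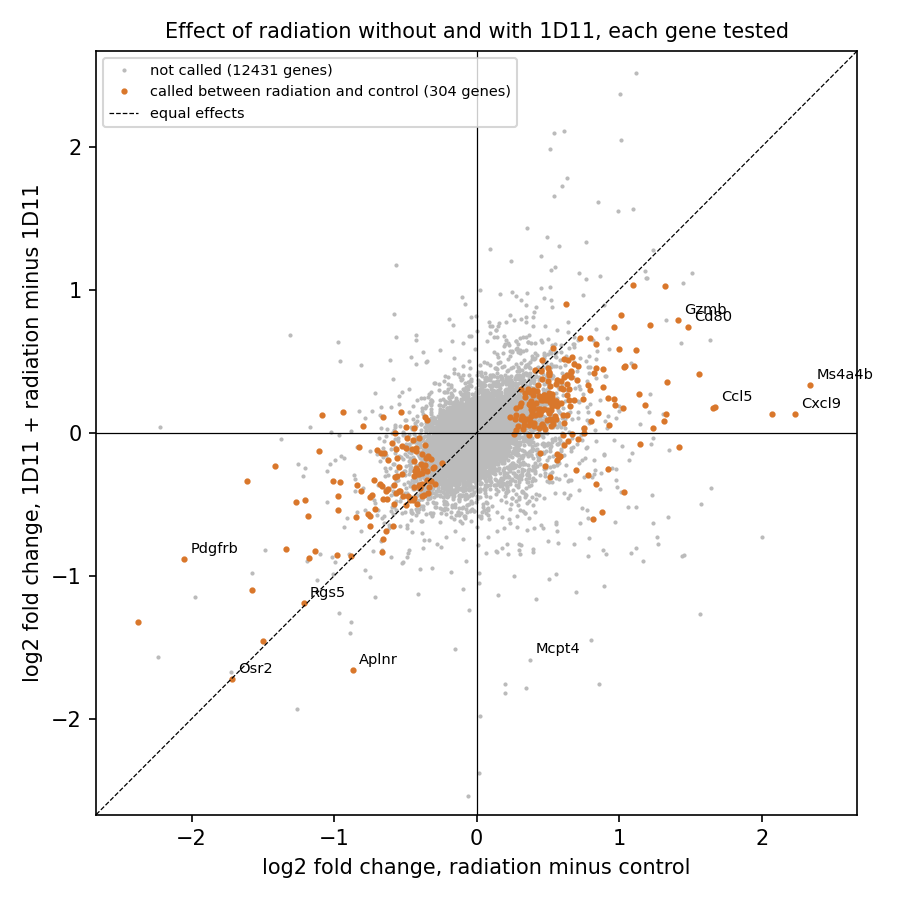
Log2 fold change of each tested gene with radiation under 13C4 (horizontal) and under 1D11 (vertical), each from 3 against 3 tumors, with the 304 genes called under 13C4 in orange. Osr2 lies on the line of equal effects at -1.72 on both axes, and Cd80 lies at 1.48 under 13C4 and 0.74 under 1D11.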

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

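The tests of epidermis, of adjacent skeletal muscle and of single arrays in this part were chosen only after the results were seen, as was the count of other splits. The lists below are given here because radiation moved them differently without and with 1D11 in camera's test of the interaction, which called 17 of 31 lists and none with an estimated correlation (smallest adjusted p = 0.260). Each value is the median interaction in log2 units, followed by the median change with radiation under 13C4 and under 1D11.

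Interferon response genes had an interaction of -0.85 (0.24 and -0.54, adjusted p = 4.19e-19, and adjusted p = 0.279 with an estimated correlation). No single tumor carried it, as the median closest to 0 with 1 tumor left out was -0.70. Skeletal muscle carried along is argued against, since the interaction of the mean scores was -0.85 ± 0.23 and -0.77 ± 0.27 with the muscle score as a covariate. With the macrophage score as a covariate it was -0.55 ± 0.30, under 2 SE, so a difference in macrophage content cannot be told apart from a change within cells. The macrophage list shares no gene with the interferon list, its abundant genes Ctsb and C1qa had 13.18 ± 0.12 and 11.77 ± 0.15 log2 intensity in control tumors, and an effect of neutralizing TGF-beta on the response to radiation may stand beside it as an open explanation.

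Mast cell, basophil and eosinophil genes had an interaction of -1.96 (0.20 and -1.59, adjusted p = 0.000196, and adjusted p = 0.279 with an estimated correlation), and their scores set the 1D11 tumors apart from the 9 others. Epidermis carried along with the tumor is argued against as the whole cause: the difference in mast cell score between 1D11 and control tumors was 0.98 ± 0.20, and 0.93 ± 0.27 with the keratinocyte score as a covariate. The mast cell protease gene Cpa3 had 10.01 ± 0.07 (SD) in 1D11 and 8.48 ± 0.89 in control tumors, whereas the keratin gene Krt14 had 7.73 ± 2.73 and 5.41 ± 0.10. Fat is argued against in the same way, with a difference of 0.81 ± 0.19 with the adipocyte score as a covariate. More mast cells in tumors with 1D11 and without radiation may be a hypothesis from these data, and another skin layer taken along was not tested.

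Macrophage genes had an interaction of -0.47 (0.32 and -0.22, adjusted p = 9.28e-08, and adjusted p = 0.311 with an estimated correlation), with Fcgr1 at -1.20 ± 0.19. MHC class II genes had -0.91 (0.81 and -0.09, adjusted p = 8.19e-05, and adjusted p = 0.311 with an estimated correlation). Dendritic cell genes had -0.55 (0.34 and -0.02, adjusted p = 0.000259, and adjusted p = 0.260 with an estimated correlation), with Cd83 at -1.45 ± 0.24. MHC class I genes had -0.23 (0.07 and -0.11, adjusted p = 0.000778, and adjusted p = 0.418 with an estimated correlation). Cytotoxic lymphocyte genes had -0.48 (0.84 and 0.26, adjusted p = 0.00673, and adjusted p = 0.418 with an estimated correlation), a call that ended without 1D11 replicate 2 (adjusted p = 0.0541) or radiation replicate 3 (0.0550), or with the muscle score as a covariate (-0.335, 0.375). MHC class I genes were at -0.14 without control replicate 3.

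Endothelial genes had an interaction of 0.39 (-0.50 and -0.14, adjusted p = 2.22e-08, and adjusted p = 0.311 with an estimated correlation). Pericyte and smooth muscle genes had 0.12 (-0.63 and -0.18, adjusted p = 0.0201, and adjusted p = 0.311 with an estimated correlation), or 0.04, 0.07, 0.00 and -0.02 without control replicate 1, 1D11 replicate 2, radiation replicate 1 or 1D11_radiation replicate 2 (adjusted p from 0.0572 to 0.236). Hypoxia and glycolysis genes had 0.25 (0.23 and 0.54, adjusted p = 5.18e-06, and adjusted p = 0.418 with an estimated correlation), and -0.02 with the muscle score as a covariate (adjusted p = 0.737). p53 targets had -0.24 (0.43 and 0.17, adjusted p = 0.000730, and adjusted p = 0.536 with an estimated correlation), or -0.08 without control replicate 1 (adjusted p = 0.518). Mitosis genes had -0.17 (0.18 and -0.02, adjusted p = 0.00115, and adjusted p = 0.635 with an estimated correlation), a call that ended without control replicate 3 (adjusted p = 0.343), 1D11_radiation replicate 2 (0.0866) or with the muscle score as a covariate (-0.08, 0.487). Hypoxia genes were at 0.395 and 0.38 without control replicate 1 or radiation replicate 1, and mitosis genes were at -0.28 and -0.08 without control replicates 1 and 3. Pericyte genes were at 0.075 without control replicate 2, 0.265 without radiation replicate 3, and 0.34 and 0.27 without 1D11_radiation replicates 1 and 3.

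Skeletal muscle markers had an interaction of -1.93 (1.17 and -0.74, adjusted p = 5.18e-06, and adjusted p = 0.466 with an estimated correlation), keratinocyte markers -0.995 (0.01 and -0.96, adjusted p = 0.000273, and adjusted p = 0.418 with an estimated correlation) and adipocyte genes -0.47 (-0.08 and -0.65, adjusted p = 0.0428, and adjusted p = 0.418 with an estimated correlation). Neutrophil genes had 0.27 (0.01 and 0.27) and inflammatory cytokines 0.16 (0.48 and 0.67), both at adjusted p = 0.0369, and adjusted p = 0.635 and 0.640 with an estimated correlation. The calls of adipocyte, neutrophil and inflammatory genes each ended in 8 of the 12 omissions of a tumor, with adjusted p up to 0.202, 0.513 and 0.5. Those were control replicates 2 and 3, 1D11 replicate 3, radiation replicates 2 and 3 and 1D11_radiation replicate 1 for all 3 lists, with control replicate 1, 1D11 replicates 1 and 2 and 1D11_radiation replicate 3 for 1 or 2 of them. With the muscle score as a covariate the inflammatory interaction changed direction, to -0.35 (adjusted p = 0.0744), and the neutrophil (0.04, 0.718) and adipocyte calls ended (-0.08, 0.495). Adipocyte genes also lost the call with the keratinocyte score (-0.28, 0.447). Skeletal muscle markers were at -1.28 without radiation replicate 3, and keratinocyte markers at -0.59 without 1D11 replicate 3. Adipocyte genes were at -0.29 without control replicate 2, and at -0.74 and -0.26 without 1D11_radiation replicates 2 and 3. Neutrophil genes were at 0.48, 0.06 and 0.16 without 1D11 replicates 1, 2 and 3, and at 0.16 and 0.18 without 1D11_radiation replicates 2 and 3. Inflammatory cytokines were at 0.42 and 0.05 without control replicates 1 and 3, 0.41, 0.04 and 0.10 without 1D11 replicates 1, 2 and 3, 0.30 and 0.04 without radiation replicates 1 and 3, and 0.28 without 1D11_radiation replicate 2.

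Among 100 splits, 3 called as many lists for the interaction as the real 17, the real split included. The highest other also called 17, and the median of the others was 9. The share of 3 in 100 is under 0.05. However, these splits move radiation labels within each antibody and so let an effect of radiation enter the interaction. Other splits also reach the same number, and no list is called with an estimated correlation, so chance is not taken as excluded here. For genes the real count was 0 (limma, 952 at an unadjusted p under 0.05), which all 100 splits reach by construction, so this count decides nothing. The highest other was 925 (with 17 lists). That split exchanges radiation labels within 1 antibody, which makes it the real comparison of radiation over both antibodies.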

How the results depend on the processing

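Leaving out both arrays with most muscle, and the muscle or keratinocyte covariate, were chosen after the results were seen. Of 68 called results for named genes, 64 kept their call with quantile normalization, 65 with the muscle covariate, 63 without both muscle-rich arrays, 61 without the filter, 52 with the mean of a gene's probe sets, and 42 each with the keratinocyte covariate and the replicate block; none of these reversed. Of 107 called lists, 101 kept their call with quantile normalization, 85 without both muscle-rich arrays, 99 without the filter, 60 of the 77 with a value at a filter of 50 percent, 103 with the mean of probe sets, 103 with the block and 0 with an estimated correlation. With the muscle covariate it was 85 of 103 and with the keratinocyte covariate 89 of 102, as the score's own list was left out. Numbers of called genes that moved by over 1.5 times follow, and the cause was not tested unless fewer tumors or another threshold is the change itself. Radiation against control (304): 747 at an adjusted p under 0.10, 890 with array weights, 573 with the muscle and 179 with the keratinocyte covariate, 569 without both muscle-rich arrays, 193 with the mean of probe sets, 6 with only the 2 groups; 20 (without radiation replicate 2) to 436 (without control replicate 1) with 1 tumor left out. 1D11 against control (2): 8 at 0.10, 13 with weights, 10 with the muscle covariate, 59 without both arrays, 4 without the filter, and 0 with the keratinocyte covariate, replicate block, quantile normalization, mean of probe sets, single probe sets or only the 2 groups (limma, 1800 at an unadjusted p under 0.05 as reported); 0 (without 1D11 replicate 1) to 21 (without control replicate 1). 1D11_radiation against radiation (0): 6 with weights and 1 without both arrays; 0 (without control replicate 2) to 1 (without control replicate 1). 1D11_radiation against 1D11 (10): 191 at 0.10, 1491 with weights, 419 without both arrays, 119 with only the 2 groups, 63 with a trended robust variance, 57 with a filter of 50 percent, 35 with the mean of probe sets, 2 with the keratinocyte covariate and 1 with the block; 1 (without 1D11_radiation replicate 3) to 227 (without control replicate 1). 1D11_radiation against control (299): 984 at 0.10, 923 with weights, 178 without the filter, 163 with the keratinocyte covariate, 85 with the block and 1 with only the 2 groups; 17 (without 1D11_radiation replicate 3) to 424 (without radiation replicate 3). Interaction (0): 122 with weights and 20 without both arrays; 0 (without control replicate 2) to 21 (without control replicate 1). Radiation over both antibodies (925): 1772 at 0.10, 2176 with weights, 1410 without both arrays and 300 with the keratinocyte covariate; 407 (without radiation replicate 1) to 1159 (without radiation replicate 3). 1D11 over both radiation states (1): 4 at 0.10, 3 each with weights, the muscle covariate or a trended robust variance, 2 each without both arrays or with quantile normalization, and 0 with the keratinocyte covariate, block or mean of probe sets; 0 (without 1D11 replicate 1) to 3 (without control replicate 2). The correlation across genes of the radiation effects without and with 1D11 (0.389) was 0.336 to 0.476 in 4 other settings and 0.198 to 0.452 with 1 tumor left out, and that of the 1D11 effects (0.025) was -0.013 to 0.050 and -0.22 to 0.16. With the muscle covariate 5 list medians reversed: matrix (0.13), p53 (-0.14), hypoxia (-0.13) and inflammatory genes (-0.12) between 1D11_radiation and radiation, and inflammatory genes in the interaction (-0.35); the cause was not tested. With 1 tumor left out DNA replication genes between 1D11 and control ran from -0.064 to 0.091 (without control replicate 1), and matrix genes in the interaction from -0.22 (without 1D11_radiation replicate 2) to 0.13. With 3 against 3 tumors an exact permutation test of a single score cannot reach p under 0.10, and signal over background per array is not known.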

Other observations

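The single genes in this paragraph and the next were picked after their values were seen, among 925 of 12735 called with radiation over both antibodies. Of 14 measured genes of MHC class I presentation 1 rose and 3 fell, and the list was not called (median -0.03, adjusted p = 0.369, and adjusted p = 0.800 with an estimated correlation). Nlrc5, a transactivator of MHC class I genes, rose by 0.58 ± 0.15 (log2 change ± SE, n = 6 against 6 tumors, adjusted p = 0.0394). The immunoproteasome gene Psmb10 (-0.35 ± 0.06, adjusted p = 0.0125), the peptide-trimming gene Erap1 (-0.30 ± 0.07) and Tapbp, the peptide-loading gene (-0.39 ± 0.10), fell. Cd274, which encodes the checkpoint ligand PD-L1, rose by 0.48 ± 0.13 (adjusted p = 0.0483).

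Of the genes for DNA repair, Ercc1 rose by 0.52 ± 0.12 (adjusted p = 0.0233) and Xrcc4 changed by -0.37 ± 0.07 (adjusted p = 0.0124) with radiation over both antibodies. With fry, which tests a list without a comparison to other genes, pericyte and dendritic genes passed between radiation and control (adjusted p = 0.00779 each), as did endothelial and cytotoxic genes (0.0319 each). Mast cell genes passed fry between 1D11 and control (adjusted p = 0.0187) and between 1D11_radiation and 1D11 (0.0131), dendritic genes for the interaction (0.0482), and pericyte genes between 1D11_radiation and control (0.0095). For radiation over both antibodies 7 lists passed fry: pericyte (0.00893), cytotoxic, hypoxia and mast cell (0.0292 each), and p53, dendritic and endothelial genes (0.0481 each). No list passed between 1D11_radiation and radiation (smallest adjusted p = 0.204) or for 1D11 over both radiation states (0.198).

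The tests of genes called between radiation and control, and counts of other splits, were chosen after the results were seen. Of the 304 genes, 254 (83.6%) still passed with the muscle score as a covariate, which argues against adjacent muscle as the main source. The muscle markers Acta1 and Myh1 had 10.93 ± 1.63 and 9.71 ± 1.43 log2 intensity in control tumors and 12.01 ± 1.08 and 10.97 ± 0.52 in radiation tumors. Without control replicates 1, 2 and 3, 221, 128 and 145 genes still passed. Without radiation replicates 1, 2 and 3, it was 37, 20 and 231. The 221 argue against control replicate 1 as the source, and an effect of radiation on these genes stays a hypothesis.

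For 3 against 3 tumors there are 10 splits, too few for a share under 0.05. The real splits called 304 genes between radiation and control (highest other 2), 2 between 1D11 and control (highest other 0), 10 between 1D11_radiation and 1D11 (highest other 0) and 299 between 1D11_radiation and control (highest other 1). In each of these, 1 split, the real one, reached that count. Between 1D11_radiation and radiation limma called 0 genes in the real split, with 688 at an unadjusted p under 0.05, all 10 splits reached that, and the highest other was 1. For lists the real splits called 16, 14, 12, 12 and 10 (radiation and control, 1D11 and control, 1D11_radiation and radiation, 1D11_radiation and 1D11, 1D11_radiation and control), against a highest other of 15, 16, 14, 15 and 12. As many lists came from 1, 2, 2, 3 and 4 of the 10 splits.

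For 6 against 6 tumors 100 splits were counted. For radiation 1 split, the real one, called as many as 925 genes, and the highest other was 30. A count that high is therefore unlikely by chance alone, at a share of 1 in 100. For 1D11 3 splits called as many as the real 1 gene, with a highest other of 2. That share is under 0.05, but another split called more genes than the real one, so chance is not taken as excluded for a count of 1. For lists, 5 splits reached the 17 called for radiation (highest other 17, median of the others 9). Of these, 1 (0 genes, 17 lists) exchanges radiation labels within 1 antibody, which makes it the real interaction. A treatment effect thus counts among the splits, and 5 in 100 lies at the threshold, so chance is neither excluded nor shown for this number. For 1D11, 57 splits reached the 9 lists called (highest other 19, median of the others 10), which is not beyond chance.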
